A study of Mus musculus with 7 samples.

How the data were processed

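The 7 single-cell libraries (10x Genomics, 5', version 2) were each pooled from 6 mice per the labels. The labels call the cells PBMC although they were taken around the implants or from the spleen. Per the submitters, Cell Ranger 5.0.1 and STAR 2.7.2a were run against mm10. The values deposited by the authors are raw UMI counts in unfiltered matrices of 32285 genes and 737280 barcodes per library. Gene positions were taken from the GENCODE annotation of the same assembly. Il10, Il12a and Il12b counts are of the mouse genes, and the source of the transgenes in the capsules is not given in the sources used here.

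A barcode was taken as a cell with at least 500 UMIs, at least 250 genes and at most 10% of UMIs on mitochondrial genes. A further rule asked for 5 times the median UMIs of the barcodes ranked 40001 to 60000, and removed nothing beyond the minimum of UMIs. Doublets were removed per library with Scrublet as built into scanpy (expected rate 0.06). Where its automatic threshold marked under 0.5% of a library, which happened in the IL10 (9 calls) and IL12 (20 calls) IP libraries, the highest scores were removed at 0.8% per 1000 cells. The removed doublets made 4.83%, 5.11%, 0.808% and 4.57% of the IL10, IL12, null and sham IP barcodes. In the spleen they made 3.46%, 3.72% and 2.65% (IL10, IL12, null). Scrublet was switched to exact neighbours after a first run had been seen. Depth limits genes of a few counts per class most in the null IP library with its 11639153 UMIs in cells.

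The 4 IP libraries were clustered together and the 3 spleen libraries together, without batch integration. Counts per cell were scaled to 10000 and log-transformed, 2000 variable genes without variable segments of immunoglobulin and T cell receptor genes, mitochondrial and ribosomal protein genes gave 30 principal components, and 15 neighbours gave Leiden clusters at resolution 1.0. Markers of 20 classes were fixed before the data were examined. The rule that scores clusters on these markers was set after looking at clusters, and was revised 3 times, the last revision so that a large IP cluster of low depth would not be named erythroid, although erythroid was its best class (score 0.71) with 5 markers detected and haemoglobin genes as 3 of its 10 most distinct genes. In its final form a cluster takes the class with the highest mean marker z-score that has at least 3 markers, and at least 1 of every 3, detected above the mean at 50 CPM or more, has a marker among the cluster's 10 most distinct genes, and has no other class with more of them. In 5 clusters another class scored higher but failed the other conditions. In the IP cavity these were a macrophage cluster with 361 null and 316 sham cells (eosinophil 0.38, macrophage 0.21), a dendritic cluster of 609 cells (plasmacytoid dendritic 1.43, dendritic 1.28) and a fibroblast cluster of 33 cells (mesothelial 4.80, fibroblast 4.62). In the spleen they were a dendritic cluster of 702 cells (plasmacytoid dendritic 2.67, dendritic 1.61) and a macrophage cluster (erythroid 2.47, macrophage 1.56) with 232 null, 123 IL12 and 9 IL10 cells, which held nearly all null spleen macrophages. Clusters that met no class stayed unnamed. In the IP cavity, an unnamed cluster took 17.8% of the IL12 and 6.73% of the null cells, another 6.62% of the IL12 and 0.284% of the null cells, and a last 1.31% of the sham, 0.957% of the IL10 and 0.390% of the null cells. The most distinct genes of this last cluster came from a single barcode with testis transcripts, and without it the 10 most distinct genes of the other 165 cells hold 2 macrophage markers and 4 proliferation genes, so that barcode kept macrophage-like cells unnamed. Macrophages and monocytes were also taken as a joint class, which was added after seeing the data because the line between them moved with the settings. Cells were sexed by transcripts: Xist cells held Xist and none of the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d, and Y cells the reverse, a split added after seeing the data. Shares of the spleen were also taken with erythroid cells left out of the total, again after seeing the data. Values for Xist cells and Y cells need at least 20 cells in both libraries.

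Class shares are percentages of all cells of a library with exact binomial 95% intervals, and their differences carry Newcombe intervals. For genes, raw counts were summed over a class and scaled to the class total to give CPM, with exact Poisson intervals, and ratios of CPM carry exact conditional intervals. A gene is called at least N-fold higher against a library with 0 counts by setting that library to 3 counts. The 26 gene lists were fixed before the data were examined too, and a list's value is the median over its members of the log2 CPM ratio with 10 CPM added to both, over members with at least 20 counts in the pair, in classes of at least 50 cells in both libraries, with an interval from 1000 Poisson redraws. List medians were also placed among 10000 random lists matched on expression, as a description that is not printed. A member is higher or lower by size where its CPM differs at least 2-fold and its interval excludes 1. As each group is 1 library, no test across mice could be made, no p-values are given, and every interval covers counting error only.

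Named genes follow a fixed rule: per pair, in IP macrophages and in B, T and NK cells, the 4 genes with the largest and the 4 with the smallest ratio by the interval bound nearest to 1, among genes with at least 50 counts in the higher library and a CPM of at least 0.5 times that in barcodes of 1 to 50 UMIs. Variable segments of antigen receptors, mitochondrial and ribosomal protein genes, predicted genes and markers of other classes were left out. The genes Il10, Il12a, Il12b, Il10ra, Il12rb1, Il12rb2, Ifng, Cxcl9, Arg1, Gata6, Timd4, Ccr2, Foxp3 and Gzmb are named where measured, and list members with the largest sizes serve as examples. Some genes that meet these rules are not reported here. The comparisons are null against sham, IL10 and IL12 against null, and IL12 against IL10 in the IP cavity, the same without sham in the spleen, and the IP cavity against the spleen for IL10, IL12 and null. Correlations between tissues run across genes of B, T and NK cells.

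The size rule was tested on counts simulated with counting error alone (200 changed genes, 100 at each fold). The rates therefore leave out spread between cells and mice. For IL10 against null in IP macrophages (7345 genes) it recovered 89% of the 2.5-fold and 100% of the 4-fold genes and called 0.518% of the unchanged ones. For IL12 against null it recovered 76% and 96% in IP macrophages (9294 genes, 0.891% of unchanged called) and 98% and 100% in spleen B cells (10176 genes, 0.0902% called). The intervals covered the true ratio for 95.9%, 96.0% and 95.5% of genes in the same order.

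Alternatives were a minimum of 1000 UMIs per cell, a minimum of 200 UMIs and 150 genes with cells classed by their own marker counts, marker counts at the main minimum, at most 20% or 5% mitochondrial UMIs, doublets kept, Leiden resolution 2.0, TMM scaling (edgeR 4.0.16), DESeq2 1.42.0 size factors, 1 CPM added in place of 10, at least 1 or 100 counts per member, the mean of the cells' own CPM, and 10% of each class's counts subtracted as ambient profile. TMM moved the median of all genes by over 0.1 in log2 in 25 of 54 pairs and classes (-0.42 to 0.36) and DESeq2 size factors in 27 of 54 (-0.45 to 0.47). Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3.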

Results

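Single-cell RNA sequencing was used to profile immune cells of C57BL/6 mice with implanted microcapsules. The capsules held engineered cells that secrete interleukin 10 (RPE-IL10, here IL10) or interleukin 12 (RPE-IL12, here IL12), non-engineered cells (RPE-null, here null), or no cells (sham). What RPE stands for is not given in the sources used here. Cells around the implants in the intraperitoneal (IP) cavity were sampled for all 4 implants, and the spleen for IL10, IL12 and null, which makes 7 libraries. Each library pooled 6 mice and had no replicate, so all intervals cover counting error alone. The sham library carries the word null in its treatment tag and sham in its title and source, and was taken as sham. The IP libraries held 27864663 (IL10), 55688795 (IL12), 13108494 (null) and 30132951 (sham) UMIs, and the spleen libraries 37847391 (IL10), 129876194 (IL12) and 50614858 (null). After filtering, 5749, 6071, 2822 and 7641 IP cells and 8625, 10808 and 10739 spleen cells remained in the same order. The median cell held 2607, 6617, 2968 and 2881 UMIs in the IP libraries and 2797, 5109 and 2773 in the spleen, so both IL12 libraries were the deepest of their tissue. Mitochondrial transcripts took a median of 1.31%, 2.0%, 2.49% and 1.57% of a cell's UMIs in the IP libraries and 0.699%, 1.72% and 1.23% in the spleen.

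Macrophages and monocytes together made up 61.8% (60.6 to 63.1) of the IL10 IP cells, 54.1% (52.8 to 55.3) of the IL12, 49.7% (47.8 to 51.5) of the null and 40.7% (39.6 to 41.8) of the sham IP cells (exact binomial 95% intervals). B cells were the largest class of the spleen, with 39.7% (IL10), 33.1% (IL12) and 40.5% (null), and T cells followed in the IL10 and null spleens. In the IL12 spleen, erythroid cells came next to B cells with 18.1% (17.4 to 18.8). Of the IL12 IP cells, 24.5% lay in clusters that met no class, most of them of low depth, against 7.41% of the null, 1.01% of the IL10 and 1.33% of the sham IP cells. Macrophages and monocytes of different implants mostly fell into different clusters, and the line between the classes moved with processing, so joint values are also given.

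**Figure D1:**
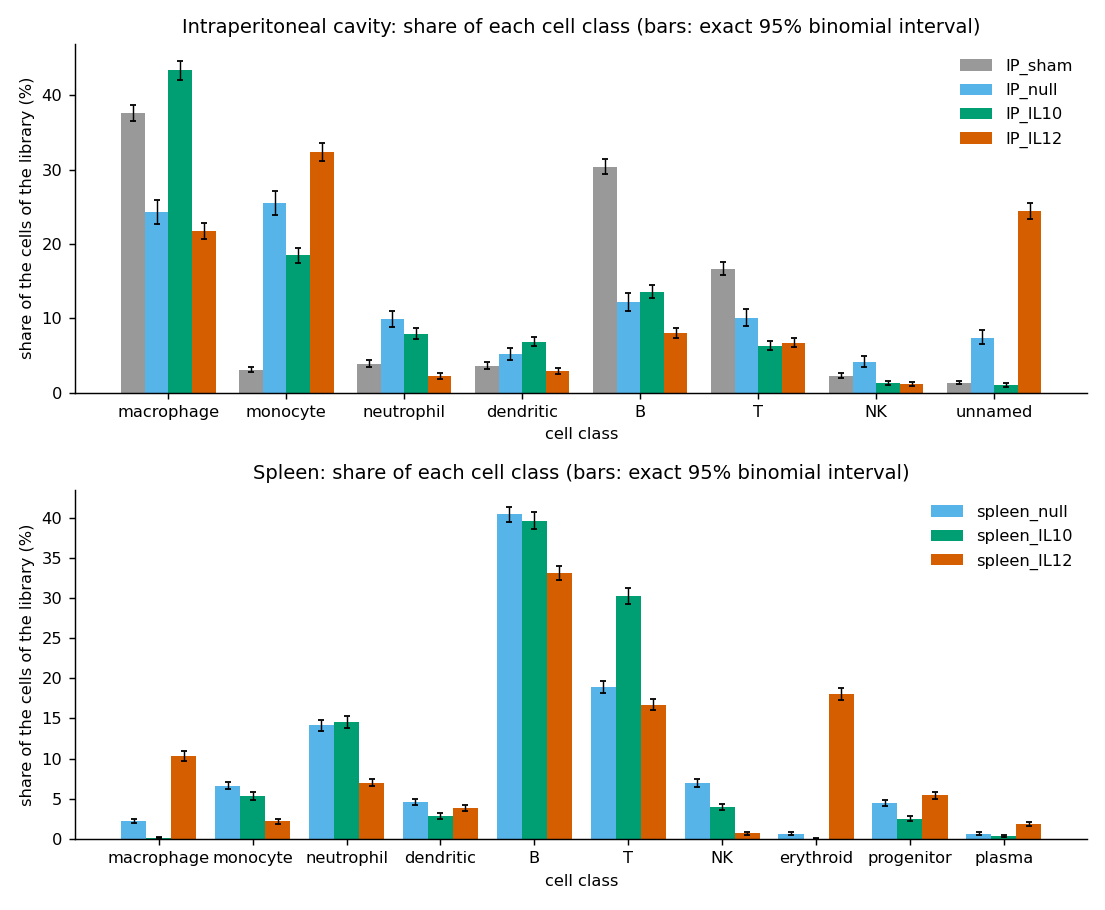
Share of each cell class among the cells of a library (percent, y axis) by class (x axis) in the IP cavity and the spleen, with bars coloured by implant and lines for exact 95% binomial intervals. Macrophages span 21.7% (IL12) to 43.4% (IL10) of the IP cells, and erythroid cells reach 18.1% of the IL12 spleen against 0.643% of the null spleen.

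The null and sham implants were compared in the IP cavity to ask what encapsulated non-engineered cells add to the capsule alone. Genes induced by interferon-gamma were higher in null macrophages: over 27 measured members the median log2 ratio was 1.43 (1.27 to 1.59), with 22 members at least 2-fold higher and 0 lower. The chemokine gene Cxcl9 stood at 123 against 3.61 CPM (counts scaled to the class total), a ratio of 34.1-fold (23.7 to 50.3), and the interferon-inducible GTPase gene Iigp1 at 114 against 1.6 CPM. Only 26 of 684 null macrophages held Cxcl9, and 1 cell gave 21.2% of its counts. The counting interval leaves out such spread between cells. Arg1, the arginase of alternatively activated macrophages, reached 2964 against 284 CPM, Chil3 4590 against 563 CPM and the osteopontin gene Spp1 344 against 20.7 CPM. The apolipoprotein gene Apoe went the other way, at 894 against 9896 CPM. Among macrophages and monocytes the interferon-gamma median was 2.02 (1.85 to 2.1) in all cells. It was 2.4 (2.2 to 2.5) in cells with Y transcripts alone and -0.55 (-0.69 to -0.20) in cells with Xist alone, a split made after seeing the data. Of the 1402 null macrophages and monocytes 286 held Y transcripts alone and 101 Xist alone, so most were in neither set.

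Within the null IP library itself, cells with Y transcripts exceeded cells with Xist by 2.18 (1.94 to 2.43) on this list (286 and 101 macrophages and monocytes). There Cxcl9 was 295 CPM in Y cells and 2.35 CPM in Xist cells (1 count) and Gbp2 699.9 and 37.6. The same contrast was -0.63 (-0.77 to -0.46) in the sham, -0.025 (-0.17 to 0.19) in the IL10 and -0.024 (-0.051 to 0.0010) in the IL12 IP library. Female and male mice were thus pooled, with Xist cells making up 34.5% of the sexed cells in the null, 72.8% in the sham, 41.0% in the IL10 and 62.5% in the IL12 IP library.

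**Figure D2:**
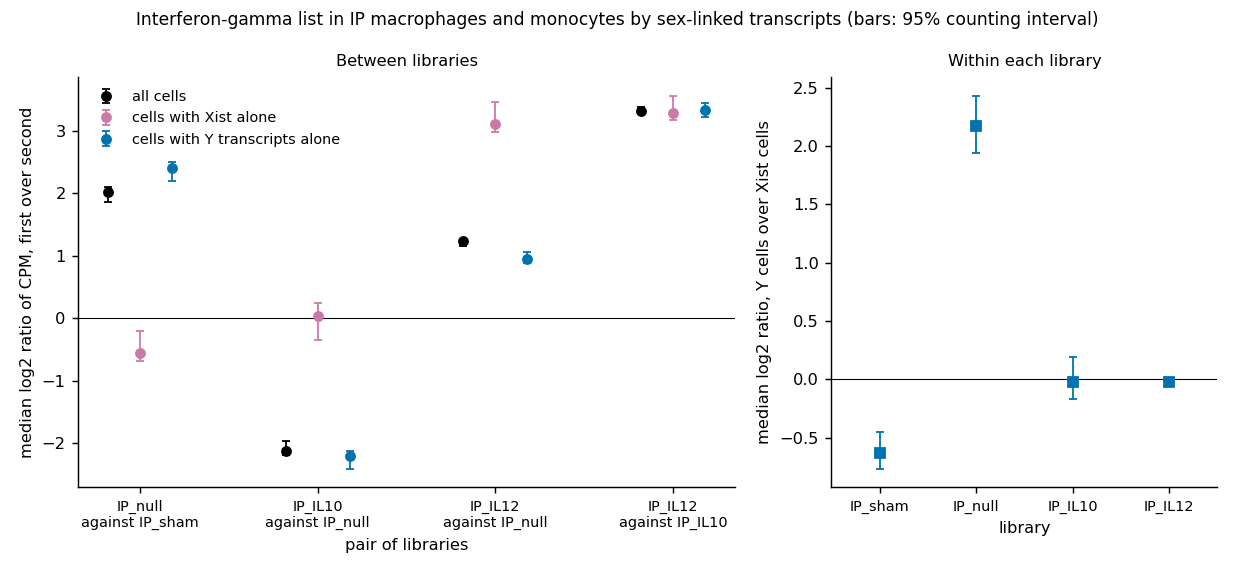
Median log2 ratio of the interferon-gamma list in IP macrophages and monocytes (y axes) between libraries (left, by pair and by cells used) and for Y cells over Xist cells within each library (right), with 95% counting intervals. Null against sham is 2.40 in Y cells and -0.55 in Xist cells, and within the null library Y cells exceed Xist cells by 2.18.

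The macrophages of null and sham differed in further groups of genes. Of the 16 glycolysis and hypoxia genes 8 were higher by size in null and 1 lower (median 0.88, 0.76 to 1.03), among them Pgk1 (365 against 105 CPM) and Tpi1 (268 against 77.2 CPM). The list of alternative activation was mixed, with 6 members higher, 4 lower and a median of 0.21 (-0.031 to 0.40), and Ccl24 stood at 1354 against 330.5 CPM. So was that of fibrosis and foreign body genes (7 higher and 3 lower of 19, median 0.076, 0.038 to 0.38), in which Timp1 (49.9 against 1.0 CPM) and Mmp14 (37.6 against 1.4 CPM) were higher and Thbs1 (508 against 2042 CPM) lower. Ccl24 is among the 10 most distinct genes of a cluster with 361 of 684 null and 316 of 2876 sham macrophages, which scored higher for eosinophils. MHC class II genes had a median of 0.40 (0.26 to 0.75, 4 of 13 higher), with H2-Aa at 1919 against 861 CPM, and type I interferon genes 0.51 (0.38 to 0.71, 8 of 17 higher). Complement genes C3 (559.8 against 64 CPM) and Cfb (529 against 37.7 CPM) led a complement list of median 0.22 (-0.016 to 0.31, 6 of 20 higher). Genes of resident peritoneal macrophages (-0.16, -0.25 to 0.020) and of lipid handling (-0.081, -0.25 to 0.023) stayed near 0, while those of monocyte-derived macrophages had a median of 0.73 (0.54 to 0.83, 7 higher and 3 lower of 18). In Xist cells alone the medians of MHC class II, type I interferon and monocyte-derived genes were -0.96, -0.32 and -0.98, and the last was -0.56 in Y cells. The uncharacterised gene AA467197 (316 against 3.71 CPM), Gbp4 (55.7 against 0.902 CPM) and Serpina3g (55 against 0.902 CPM) had some of the largest ratios in favour of null. Cxcl1 (3.62 against 141 CPM), Jun (29.7 against 479 CPM) and Hes1 (8.68 against 154 CPM) some of the largest in favour of sham. Of the 19 immediate-early and heat-shock genes that respond to cell handling, 12 were lower in null (median -1.95, -2.03 to -1.63, Fos 67.3 against 660.1 CPM), and mitochondrial transcripts were higher (1.13, 1.06 to 1.16). In monocytes the interferon-gamma median was 1.47 (1.37 to 1.73) and the handling median -1.21 (-1.38 to -1.09).

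Null T cells held more transcripts of proliferation genes than sham T cells: 21 of 24 proliferation genes were higher by size (median 1.64, 1.44 to 1.77), with Mki67 at 117 against 10.5 CPM and Birc5 at 113 against 6.64 CPM. In Xist cells alone this median was 0.039, and that of the interferon-gamma list 0.0047. Their type 1 lymphocyte genes had a median of 0.74 (0.57 to 0.89, 11 higher and 2 lower of 23), with granzyme B (Gzmb) at 90.8 against 9.76 CPM and the IL12 receptor gene Il12rb2 at 27.8 against 1.95 CPM, but the median was -0.24 in Xist cells alone, and Y cells were 75.6% of the sexed T cells in null and 19.0% in sham. The interferon-gamma list was 0.72 (0.63 to 0.83, 11 of 24 higher) in T cells, 0.45 (0.33 to 0.53, 6 of 20 higher) in B cells, 0.65 (0.50 to 0.89, 6 of 18 higher) in NK cells and 2.7 (2.5 to 3.03) in neutrophils, where Gbp2 reached 1356 against 51.5 CPM. NK cells of null held more Gzmb (375 against 102 CPM), Pim2 (325 against 107 CPM) and Hist1h4d (101 against 22 CPM). They held less Fos (11.5 against 648 CPM), Dusp1, Fosb and Ppp1r15a. In T cells, Hist1h2ap (179.6 against 8.98 CPM) and Hist1h2ae (237 against 16.4 CPM) were higher. Fos, Fosb, Ppp1r15a and Peg13 (1.36 against 30.4 CPM) were lower, and Lgals7 was seen in 6 null cells only. B cells had Itgb3 (24.5 against 0.918 CPM), Rflnb (28.2 against 2.45 CPM), Satb1 and Snx29 higher. Fosb (1.82 against 29.5 CPM), Ppp1r15a and Ahnak2 were lower there, and Pcsk1n came from 3 sham cells. The handling median was below 0 in null T cells (-1.75, -1.9 to -1.55) and B cells (-0.79, -0.86 to -0.62, 7 of 16 lower) too. The null shares less the sham shares were -18.2 points (-19.8 to -16.6) for B cells, -6.63 points (-7.99 to -5.21) for T cells and 22.4 points (20.7 to 24) for monocytes, and smaller for NK cells (1.88 points, 1.12 to 2.74), neutrophils (5.96 points, 4.82 to 7.19) and dendritic cells (1.53 points, 0.651 to 2.49). Macrophages and monocytes together differed by 8.97 points (6.82 to 11.1), which came down to 0.0648 at 20% mitochondrial UMIs. The macrophage share alone, at -13.4 points (-15.3 to -11.5), turned to 7.76 points at a minimum of 1000 UMIs per cell and changed direction under 4 other planned settings. The monocyte interferon-gamma median also turned, to -0.79 at that minimum and to -0.79 at 5% mitochondrial UMIs.

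The IL10 and null implants were compared in the IP cavity to ask what secreted IL10 changes around the capsules. Macrophages of the IL10 library held far more Cd163, the scavenger receptor for haemoglobin, at 472 against 3.62 CPM, a ratio of 130.5-fold (55.8 to 402). The efferocytosis ligand gene Gas6 (121 against 2.17 CPM), Cbr2 (404 against 19.5 CPM), Folr2 (324 against 21.7 CPM), Lyve1 (192 against 10.8 CPM) and Spp1 (1724 against 344 CPM) were higher as well. The chemokine gene Ccl8 was at least 23.6-fold higher (51.1 CPM, 0 counts in null). Other genes of alternative activation were lower, namely Chil3 (168 against 4590 CPM) and Retnla (1451 against 6014 CPM), and that list as a whole had 9 members higher and 6 lower of 20 (median 0.44, 0.26 to 0.65). Retnla is among the 10 most distinct genes of a cluster with 361 of 684 null and 65 of 2493 IL10 macrophages, which scored higher for eosinophils. Interferon-gamma genes were lower, with 25 of 26 members lower by size and a median of -1.48 (-1.7 to -1.42): Cxcl9 stood at 1.71 against 123 CPM, Iigp1 at 0.214 against 114, Gbp4 at 0.428 against 55.7 and Serpina3g at 1.07 against 55. In macrophages and monocytes together the median was -2.13 (-2.19 to -1.97) in all cells and -2.2 (-2.41 to -2.13) in Y cells (670 and 286), but 0.036 (-0.35 to 0.25) in Xist cells (157 and 101, 9 members). Null Xist cells already lay 2.18 below Y cells on this list, with little room to fall, so the Xist value cannot tell the direction.

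Antigen presentation was lower in IL10 macrophages, with 8 of 12 MHC class II genes (median -1.12, -1.17 to -0.93, H2-Ab1 731 against 1931 CPM) and 9 of 18 MHC class I genes (-0.86, -0.99 to -0.72, Tap1 25.5 against 91.1 CPM) lower by size. Both of these turned in Xist cells alone, to 0.52 and 0.46. The 22 measured genes of the IL10 and STAT3 response had a median of 0.22 (0.15 to 0.40), with 8 higher and 2 lower, led by Cd163 and the metallothionein gene Mt2 (123 against 7.23 CPM). Inflammatory mediators were mixed (9 higher and 3 lower of 20, median 0.46, 0.34 to 0.69): Ccl3 (43.7 against 5.06 CPM) and Cxcl1 (33.4 against 3.62 CPM) were higher and Acod1 (2.14 against 82.4 CPM) lower. Fibrosis and foreign body genes stayed near 0 as a list (0.028, -0.10 to 0.19), with Trem2 (211 against 83.9 CPM) higher and Mmp14 (10.1 against 37.6 CPM) lower. The lists of lipid handling (0.093, -0.10 to 0.22, Apoe 3039 against 894 CPM and Cd36 15.8 against 121 CPM) and complement (0.20, -0.023 to 0.24, Cfb 39.8 against 529 CPM) likewise held members of both directions. Type I interferon genes had a median of -0.57 (-0.74 to -0.47, 8 of 17 lower) and those of monocyte-derived macrophages -0.93 (-1.24 to -0.73), the last turning to 0.56 in Xist cells alone. The acute-phase gene Saa3 was abundant, at 54190 against 21310 CPM. The resident list had a median of -0.43 (-0.53 to -0.22, 5 higher and 6 lower of 24) but turned to 0.93 at a minimum of 1000 UMIs per cell. Of the IL10 macrophages, 2105 of 2493 lay in a cluster with a median depth of 1114 UMIs that Cd163, Cbr2, Folr2, Lyve1 and Gas6 help define, while null macrophages lay mostly in a pair of others. The handling median was above 0 in IL10 (0.70, 0.55 to 0.97, 9 of 19 higher in macrophages and 1.42, 1.28 to 1.51 in monocytes, Fos 379.7 against 67.3 CPM in macrophages) and that of mitochondrial transcripts below 0 (-0.89, -0.92 to -0.86, 4 of 12 lower). In the monocyte class the interferon-gamma median was -2.22 (-2.35 to -2.11), with Gbp2 at 19.2 against 707 CPM, but -0.22 at a minimum of 1000 UMIs and -0.12 at 5% mitochondrial UMIs.

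Interferon-gamma medians were below 0 in lymphocytes around the IL10 implants too: -0.61 (-0.74 to -0.49, 10 of 24 lower) in T cells (Gbp2 47.5 against 199 CPM), -0.46 (-0.56 to -0.34, 6 of 20 lower) in B cells (Socs1 14.7 against 50.9 CPM), -0.76 (-0.89 to -0.41, 6 of 19 lower) in NK cells and, among myeloid cells, -2.8 (-3.02 to -2.62) in neutrophils. Type 1 lymphocyte genes of T cells had a median of -0.49 (-0.63 to -0.37, 4 higher and 7 lower of 23), with Il12rb2 at 2.93 against 27.8 CPM and Gzmk at 83.2 against 18.3 CPM. Restricted to Xist cells, the B cell interferon-gamma median was 0.050 and the type 1 median of T cells 0.47, the latter from 104 IL10 and 33 null cells. Immediate-early genes were higher in T cells (Junb 542 against 156 CPM and Ppp1r15a 104 against 9.49 CPM, handling median 1.1, 0.83 to 1.27) and B cells (Fosb 18.9 against 1.82 CPM, 0.73, 0.62 to 0.93). B cells also held more Ccr6 (109.6 against 26.8 CPM), Dusp2 (95.8 against 20.9 CPM) and Pxdc1, and less Itgb3, Il9r and Ighg2b, the last from 6 null cells. Furin was lower in T cells (34.6 against 146 CPM) and in NK cells (19.5 against 111 CPM). Rnf213 was lower in NK cells too, and Hmgn2, Hspe1, Nme2 and Ccl4 (2059 against 656 CPM) were higher, but of their counts in 73 IL10 NK cells the largest cell gave 31.0%, 30.65%, 21.2% and 42.1%. Single cells gave most counts of Ccl4 (84.4%) and Gcg (83.6%) in IL10 T cells and of Mt3 (63.2%) and Lgals7 (69.5%) in null T cells. Macrophages and monocytes together took 12.2 points (9.92 to 14.4) more of the cells than in null and dendritic cells 1.7 points (0.621 to 2.72). The joint value ranged from 1.72 with a minimum of 200 UMIs and marker counts per cell to 25.4 at 20% mitochondrial UMIs. T cells (-3.75 points, -5.06 to -2.51) and NK cells (-2.88 points, -3.72 to -2.13) took less and B cells differed by 1.4 points (-0.13 to 2.87). The macrophage share alone, 19.1 points (17.1 to 21.1), turned to -7.53 points at a minimum of 1000 UMIs per cell. The monocyte share, -6.97 points (-8.88 to -5.09), turned under 3 settings.

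**Figure D3:**
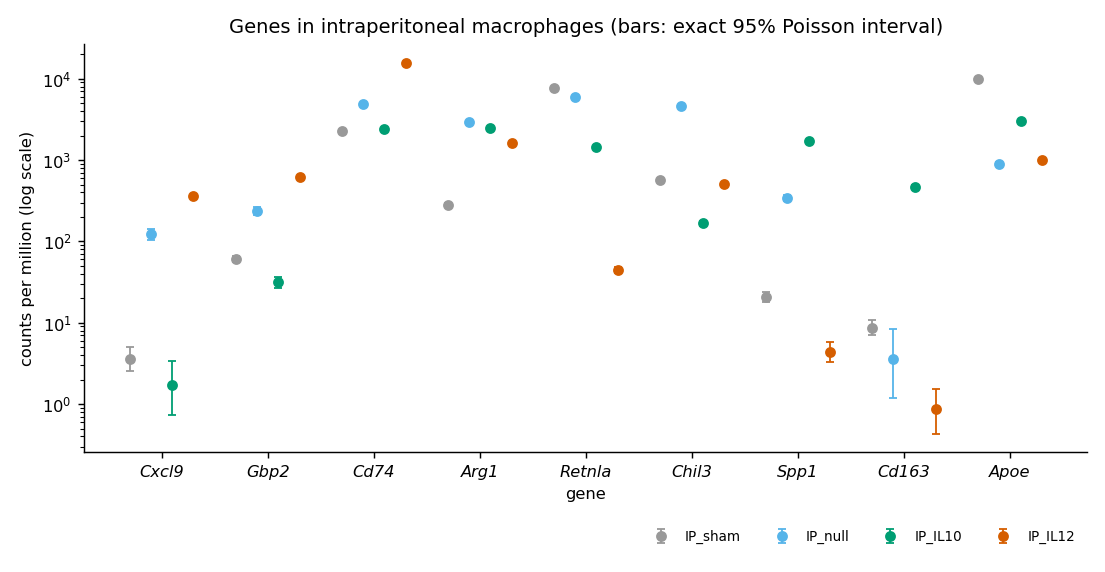
Expression of 9 genes (x axis) in IP macrophages in CPM on a log scale (y axis) by implant, with exact 95% Poisson intervals. Cd163 is at 472 CPM with IL10 against 0.868 to 8.72 CPM in the other libraries, and Cxcl9 at 361 CPM with IL12 against 1.71 CPM with IL10.

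The IL12 and null implants were compared in the IP cavity to ask what secreted IL12 changes there. In T cells Ifng, which encodes interferon-gamma, stood at 1350 against 55.6 CPM, a ratio of 24.3-fold (19.6 to 30.6), and Il12rb2 at 98.7 against 27.8 CPM. Of the 25 type 1 lymphocyte genes 14 were higher by size and 2 lower (median 1.06, 0.92 to 1.21), with the perforin gene Prf1 at 101 against 19 CPM, Gzmb at 293 against 90.8 CPM and Xcl1 at 646 against 118 CPM. Proliferation genes were higher (19 of 24, median 1.49, 1.35 to 1.59, Ube2c 622 against 81.3 CPM) and naive T cell genes lower (12 of 13, median -1.61, -1.76 to -1.35, Ccr7 19.9 against 142 CPM and Il7r 67.8 against 292 CPM). Foxp3, the transcription factor of regulatory T cells, was at 5.46 against 52.9 CPM, whereas Il2ra was at 207 against 82.7 CPM, and the regulatory list had a median of -0.34 (-0.50 to -0.22, 2 higher and 3 lower of 11). The T activation list had a median of 0.48 (0.31 to 0.64, 5 higher and 1 lower of 17), with Ldha at 1766 against 539.5 CPM and Batf at 204 against 69.8 CPM. Gstt1, Irx3 and Serpinb5, each without a count in null, were at least 70.9-fold, 39.2-fold and 30.6-fold higher, and the purinergic receptor gene P2rx3 stood at 80.2 against 0.678 CPM. Tmem108 (1.06 against 44.7 CPM), Pde2a (8.64 against 84.7 CPM) and the cytokine receptor genes Il6ra (2.88 against 38.6 CPM) and Il4ra (15.8 against 136 CPM) were lower. The interferon-gamma list of T cells was 0.34 (0.23 to 0.54, 4 higher and 2 lower of 25), Gbp2 being at 728 against 199 CPM, and their handling list 0.58 (0.36 to 0.75, 5 of 15 higher). Of the IL12 T cells, 318 lay in a cluster of 390 cells that held 43 of null, whereas null T cells lay mostly in clusters shared with the other implants.

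NK cells of the IL12 library followed with Ifng at 1003 against 57.4 CPM, Gzmb at 2819 against 375 CPM and Ly6a at 3925 against 411 CPM, in a type 1 list of median 1.22 (0.94 to 1.46). Their Klrb1c (71 against 647 CPM), Itga4 (48.7 against 276 CPM), Bcl2 (44.7 against 241 CPM) and Ssh2 were lower. Their proliferation median was 0.54 (0.14 to 0.73, 4 of 13 higher), and their interferon-gamma median 0.057 (-0.086 to 0.36) spanned 0. P2rx3 and the agouti gene (symbol a) had 84 and 101 counts in IL12 and none in null NK cells, and 57.2% of the Gzmc counts came from 1 cell. B cells held more of the interferon-gamma list (22 of 25 higher, median 1.89, 1.78 to 2.03), with Iigp1 at 134 against 1.82 CPM, Gbp6 at 69 against 1.36 CPM and Gbp10 at 38.2 against 0.455 CPM. Ifit3 and the chemokine receptor gene Cxcr3 had no count in null B cells and were at least 21.6-fold and 15.4-fold higher. Lifr (14.7 against 97.7 CPM), S100a4 (109.6 against 562 CPM), Polr2l and Snx29 were lower. The B cell handling list was 0.56 (0.40 to 0.75, 6 of 15 higher). Of the 486 IL12 B cells 435 lay in a cluster that held 15 null cells, while null B cells lay mostly in a pair of others (210 and 115).

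Macrophages with IL12 had all 30 measured interferon-gamma genes higher by size (median 1.61, 1.52 to 1.7), with Cxcl10 at 139 against 8.68 CPM, Socs1 at 201 against 20.2 CPM and Cxcl9 at 361 against 123 CPM. The median came down to 0.82 at a minimum of 1000 UMIs, 0.92 at 5% mitochondrial UMIs and 0.82 at Leiden resolution 2.0. Under these settings those of MHC class I genes were 0.39, 0.45 and 0.43, and of resident macrophage genes -0.30, -0.22 and -0.17. MHC class II genes (7 of 14 higher, median 0.86, 0.73 to 0.93, Cd74 15760 against 4905 CPM), MHC class I genes (1.08, 1.01 to 1.12, Psmb8 1216 against 276 CPM) and type I interferon genes (0.72, 0.60 to 0.88, Isg15 145 against 36.9 CPM) were higher. The nitric oxide synthase gene Nos2 was at 76.4 against 4.34 CPM while Il1b (13 against 73.8 CPM) and Il6 (4.34 against 34 CPM) were lower, and the inflammatory list had a median of 0.071 (-0.18 to 0.18). Genes of alternative activation were lower (9 of 18 and 0 higher, median -0.83, -0.92 to -0.63), led by Retnla at 45 against 6014 CPM, a ratio of 134-fold (123 to 146), and Ccl24 at 15.2 against 1354 CPM. Retnla, Ccl24 and Fcrls are among the 10 most distinct genes of a cluster with 361 of 684 null and 27 of 1318 IL12 macrophages. That cluster scored higher for eosinophils (0.38) than for macrophages (0.21), so these ratios also carry the difference in its share. Fibrosis and foreign body genes were lower (11 of 19, median -0.74, -1.01 to -0.64), with Spp1 at 4.42 against 344 CPM, Thbs1 at 40.7 against 508 CPM and Timp1 at 0.947 against 49.9 CPM. Of the resident macrophage genes 17 of 24 were lower (-1.2, -1.28 to -1.08, Prg4 251 against 1133 CPM), though the efferocytosis receptor gene Timd4 was higher at 83.1 against 18.1 CPM. Arg1 was at 1629 against 2964 CPM. Among the largest ratios were Ccl5 (453 against 23.1 CPM), Upp1 (434 against 27.5 CPM) and Calhm6 (362 against 29.7 CPM) upwards and Fcrls (0.474 against 40.5 CPM) downwards, the last turning at a minimum of 1000 UMIs per cell. Complement genes C1qa, C1qb (5834 against 1614 CPM) and C1qc were higher in a list of median 0.18 (0.12 to 0.30), and the monocyte-derived list, -0.077 (-0.33 to 0.21), combined a higher Ly6c2 (672 against 26.8 CPM) with a lower Ccr2 (68.5 against 431 CPM). IL12 macrophages lay mostly in a pair of clusters (1075 and 215 cells) of which the larger held 19 cells of other libraries. Their handling list was -0.23 (-0.35 to -0.090).

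The interferon-gamma median of monocytes was 1.13 (1.06 to 1.2), that of macrophages and monocytes together 1.24 (1.15 to 1.27), and that of neutrophils 2.13 (2.04 to 2.32), where Gbp4 stood at 1740 against 58.6 CPM. These classes lay in different clusters too: 122 of 132 IL12 neutrophils in one and 237 of 278 null neutrophils in another, and 1915 of 1964 IL12 monocytes in one that held 19 null cells. In Xist and Y cells of the joint class it was 3.1 (2.97 to 3.46) and 0.94 (0.89 to 1.06). B cells (-4.18 points, -5.6 to -2.83), T cells (-3.32 points, -4.63 to -2.08), NK cells (-3.01 points, -3.84 to -2.27), neutrophils (-7.68 points, -8.88 to -6.56) and dendritic cells (-2.22 points, -3.18 to -1.34) took smaller shares with IL12 than with null. The joint share of macrophages and monocytes, 4.38 points (2.15 to 6.61), turned to -15.1 points at a minimum of 1000 UMIs per cell, and turned under 4 other settings. The monocyte share (6.91 points, 4.9 to 8.88) turned under 5 settings, and the macrophage share (-2.53 points, -4.44 to -0.657) at 20% mitochondrial UMIs and in the joint class.

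**Figure D4:**
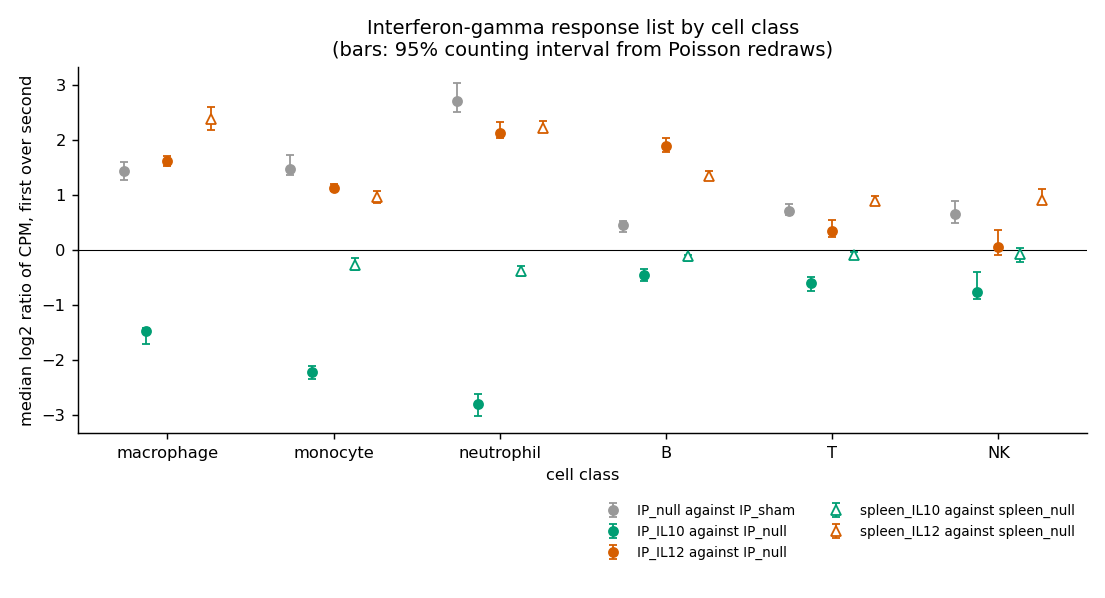
Median log2 ratio of the interferon-gamma list (y axis) by cell class (x axis) for each implant against null, and for null against sham, with filled circles for the IP cavity, open triangles for the spleen and 95% counting intervals. Medians run from -2.80 (IP neutrophils, IL10 against null) to 2.7 (IP neutrophils, null against sham), and spleen IL10 against null stays between -0.39 and -0.07.

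Set against each other, the IL12 and IL10 implants gave the widest interferon-gamma differences in the IP cavity. All 30 interferon-gamma genes were higher by size in IL12 macrophages, with a median of 3.28 (3.22 to 3.37), Iigp1 at 368 against 0.214 CPM, Ly6i at 283 against 0.428 CPM, and Serpina3g and Gbp4 higher as well. This held in Xist cells (3.28, 3.18 to 3.56) and in Y cells (3.33, 3.22 to 3.44) of the joint macrophage and monocyte class (3.31, 3.26 to 3.38 in all its cells) and in monocytes (3.38, 3.28 to 3.45). MHC class II genes were higher (11 of 14, median 1.55, 1.42 to 1.7, H2-Eb1 3674 against 428 CPM). Alternative activation (14 of 21 lower and 3 higher, median -1.17, -1.37 to -1.0) and fibrosis and foreign body genes (12 of 20 lower, -0.90, -1.05 to -0.75) were lower. Among them were Cd163 at 0.868 against 472 CPM, Spp1 at 4.42 against 1724 CPM, Gas6 at 0.158 against 121 CPM and Trem2 at 36.5 against 211 CPM. Rasgef1a had no count in IL12 macrophages and was at least 106-fold lower. T cells held more Csf1 (209 against 0.586 CPM), Ifng (1350 against 28.7 CPM), Gstt1, P2rx3 and Irx3, more proliferation genes (1.42, 1.3 to 1.53) and type 1 genes (1.08, 0.87 to 1.18). Naive genes were lower (-1.72, -1.86 to -1.57), with Tbc1d4 at 3.34 against 53.3 CPM and Tmem108, Il6ra and Pde2a lower too. Interferon-gamma medians were 0.97 (0.88 to 1.12) in T cells, 2.3 (2.19 to 2.41) in B cells, 0.81 (0.64 to 1.06, 8 of 18 higher) in NK cells and 4.84 (4.64 to 5.06) in neutrophils. B cells held more Tgtp2 (64.8 against 0.402 CPM), Gbp10 and Gbp4 (188 against 4.82 CPM), and Tgtp1 without a count in IL10. They held less Csf2rb2 (2.45 against 53.6 CPM), Hist1h2ap, Pxdc1 and Fosb. NK cells held more AA467197 (1094 against 31.7 CPM) and the checkpoint gene Pdcd1 (at least 15.1-fold), and less Ssh2, Itga4 (48.7 against 369 CPM) and Klrb1c (71 against 415 CPM), while Ighm came to 57.9% from 1 cell. Handling medians were below 0 with IL12, at -1.48 (-1.55 to -1.33) in macrophages, -1.33 (-1.38 to -1.27) in the joint class, -0.68 (-0.77 to -0.39, 2 higher and 7 lower of 17) in T cells and -0.26 (-0.45 to -0.15, 2 higher and 4 lower of 16) in B cells. The joint share of macrophages and monocytes differed by -7.78 points (-9.55 to -6.0), and by -42.2 at 5% mitochondrial UMIs, that of macrophages alone by -21.7 points (-23.3 to -20.0) and that of T cells by 0.425 points (-0.466 to 1.31). The monocyte share, 13.9 points (12.3 to 15.4), changed direction under 5 settings, to -22.1 points at a minimum of 1000 UMIs per cell.

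In the spleen, the IL10 and null implants were compared to ask whether IL10 from the capsules is seen at a distance. T cells took 11.4 points (10.2 to 12.6) more of the IL10 spleen than of the null spleen (30.3% against 18.9%), and NK cells (-2.98 points, -3.61 to -2.35), macrophages with monocytes (-3.39 points, -4.11 to -2.67) and dendritic cells (-1.75 points, -2.28 to -1.22) took less. B cells (-0.773 points, -2.16 to 0.616) and neutrophils (0.369 points, -0.621 to 1.37) did not differ beyond counting error. Interferon-gamma genes hardly differed, with medians of -0.11 (-0.19 to -0.083) in B cells (1 of 23 lower, Gbp7 6.91 against 14.6 CPM), -0.088 (-0.17 to -0.034) in T cells, -0.074 (-0.22 to 0.034) in NK cells, -0.27 (-0.37 to -0.14) in monocytes and -0.39 (-0.46 to -0.29) in neutrophils. Genes that respond to handling differed more: in B cells Fos was at 463 against 5.0 CPM, Jun at 339 against 25.2 CPM, Klf4 at 29.2 against 1.28 CPM and Fosb at 90.5 against 5.83 CPM, with handling medians of 0.48 (0.42 to 0.57) in B cells, 1.1 (1.0 to 1.2) in T cells and 1.79 (1.72 to 1.93) in monocytes. In monocytes the inflammatory chemokine genes Ccl3 (164 against 3.97 CPM) and Ccl2 (156 against 3.63 CPM) were higher beside that handling signal (list median 1.54, 1.34 to 1.67). NK cells held more proliferation genes (21 of 24, median 1.24, 1.18 to 1.43, Pclaf 203 against 9.46 CPM), more Fos, Fosb and Jun (343 against 21 CPM), and less Lfng (76.4 against 253 CPM), Zeb2 (102 against 273 CPM), Lrp6 and Brd1. In Xist cells alone that proliferation median was -0.49. T cells held less Ckb (9.51 against 30.2 CPM), Lfng (55.6 against 135 CPM), Zfp553 and Xist (126 against 328 CPM), and more Jun, Fosb and Ppp1r15a (245 against 18.3 CPM), while 54.3% of their Ifng counts came from 1 cell. B cells held less Ackr3 (5.28 against 21.1 CPM), S1pr3 (7.58 against 26.1 CPM), Tspan15 and AC113595.1. The type 1 list in T cells had a median of -0.054 (-0.10 to 0.058). The T cell interferon-gamma median turned to 0.068 with TMM scaling. Most IL10 B cells (2420) lay in a cluster with few null cells.

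The IL12 and null spleens were compared to ask the same of IL12. B cells of the IL12 spleen had 23 of 28 interferon-gamma genes higher by size (median 1.35, 1.29 to 1.43), with Socs1 at 170.4 against 7.37 CPM, Gbp6 at 56.2 against 2.37 CPM, Gbp10 at 24.6 against 0.256 CPM and Serpina3f at 133 against 3.08 CPM. It was 1.4 (1.33 to 1.59) in Xist cells and 1.71 (1.44 to 1.82) in Y cells. T cells held more Ifng (193 against 2.97 CPM, a ratio of 64.8-fold, 40.9 to 109.6), Xcl1 (642 against 60.1 CPM) and Gzmb (99.9 against 5.12 CPM). Ifng was seen in 294 of 1806 IL12 T cells, and 1 cell gave 16.7% of its counts, a spread that the interval leaves out. All 24 proliferation genes were higher by size (median 2.73, 2.66 to 2.84, Pclaf 410.2 against 12.2 CPM). Erythroid cells took 17.4 points (16.7 to 18.2) more of the cells, and NK cells (-6.23 points, -6.75 to -5.74) and neutrophils (-7.13 points, -7.95 to -6.32) less. The 1954 erythroid cells held carbonic anhydrase genes Car1 and Car2 at 2378 and 2284 CPM, the erythroid factor genes Klf1 and Gata1 at 451 and 221 CPM and the haemoglobin gene Hba-a1 at 258.5 CPM. The library's ambient profile held them at 908, 890, 181, 74.3 and 132 CPM. Haemoglobin was 0.29% of UMIs in 702 of the cells and 0.0036% in 1252.

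Type 1 genes of IL12 spleen T cells had a median of 1.29 (1.18 to 1.4), 19 of 25 being higher, and checkpoint genes 0.94 (0.81 to 1.07), with Pdcd1 at 71.8 against 7.92 CPM, Lag3 at 38 against 2.81 CPM and Cd160 at 311 against 46 CPM. Naive genes were lower (10 of 14, median -1.03, -1.1 to -0.99, Lef1 127 against 365 CPM), activation genes had a median of 0.70 (0.59 to 0.80, 7 higher and 1 lower of 17) with Tnfrsf9 at 74.7 against 19.8 CPM, and the regulatory list stayed at -0.017 (-0.089 to 0.10) with Foxp3 at 17.3 against 23.8 CPM. P2rx3 had no count in null T cells and was at least 47.9-fold higher. St8sia6 (2.46 against 19.1 CPM), Pdlim4 (5.67 against 36.8 CPM), Thra and Rflnb were lower, and Ccl1 came from 3 cells. The interferon-gamma list was higher in T cells (0.89, 0.84 to 0.98), NK cells (0.90, 0.83 to 1.11), neutrophils (2.22, 2.14 to 2.34), monocytes (0.96, 0.85 to 1.08) and macrophages (2.38, 2.17 to 2.59), the last with 992 IL12 cells in a cluster that held 4 of null. In neutrophils it was 2.33 in Xist cells and 1.39 in Y cells, and Xist cells were 67.0% of the sexed neutrophils with IL12 and 19.5% with null. The null baseline of the macrophages was mostly 232 cells of a cluster with a higher erythroid than macrophage score. Medians of B cells were above 0 for germinal centre and activation genes (0.54, 0.46 to 0.60, 8 of 20 higher, but -0.032 in Y cells alone) and MHC class I genes (0.77, 0.74 to 0.81, 4 of 18 higher, Tap1 304 against 107 CPM). Lists of B-1 cells (-0.044, -0.12 to 0.020), immunoglobulin constant regions (-0.033, -0.062 to 0.029) and ribosomal proteins (0.040, 0.025 to 0.055) stayed near 0, although Ighg2c (32.3 against 1.6 CPM), Jchain (113 against 17.6 CPM) and Tbx21 (8.0 against 0.641 CPM) were higher. Plxnd1, Tspan15 (2.0 against 10.5 CPM), Ceacam2 and the Y-linked Eif2s3y (6.72 against 22.8 CPM) were lower in B cells. NK cells held more proliferation genes (1.68, 1.54 to 1.94, Ube2c 375 against 29.9 CPM with 27.2% from 1 cell, Pclaf, Hist1h2ae) and Batf3 (189.9 against 10.5 CPM). They held less Cma1 (54.6 against 444 CPM), Klrb1c (183 against 1123 CPM), Arl4d and Sap25, and their type 1 list spanned 0 (-0.11, -0.22 to 0.16). Of the IL12 spleen cells, 2069 of 3580 B cells, 754 of 1806 T cells and 502 of 757 neutrophils lay in clusters with few null cells (107, 84 and 67). Handling medians were 0.47 (0.35 to 0.54, 4 of 16 higher) in B cells, 0.11 (0.021 to 0.21) in T cells and 0.30 (0.16 to 0.45) in monocytes. The share of T cells differed by -2.17 points (-3.19 to -1.14) and that of B cells by -7.34 points (-8.62 to -6.05), but by 1.4 and -0.288 points with the erythroid cells left out of the total, a choice made after seeing the data. The macrophage share (8.12 points, 7.49 to 8.76) and the monocyte share (-4.46 points, -5.02 to -3.92) both turned when each cell was classed by its own marker counts, to -0.0881 and 2.9 points. The neutrophil share turned under 1 setting.

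The IL12 spleen set against the IL10 spleen gave interferon-gamma medians of 1.57 (1.52 to 1.64) in B cells, 1.13 (1.08 to 1.19) in T cells, 1.2 (1.03 to 1.35) in NK cells, 1.32 (1.21 to 1.43) in monocytes and 2.61 (2.49 to 2.69) in neutrophils. B cells held more Serpina3f (133 against 2.59 CPM), Socs1 (170.4 against 5.66 CPM), Gbp10 and Gbp6, and less Fos (11.9 against 463 CPM), Rhob (10.1 against 108 CPM), Klf4 and Ppp1r15a. In T cells, proliferation genes (2.7, 2.64 to 2.79, Ube2c 480.0 against 9.38 CPM, Ccna2 125 against 2.38 CPM), type 1 genes (1.29, 1.18 to 1.45) and checkpoint genes (0.76, 0.65 to 0.89) were higher with IL12, as were P2rx3 and Gstt1. Naive genes (-0.93, -1.02 to -0.85) were lower. The Y-linked Kdm5d (0.851 against 11.8 CPM) and Ddx3y (2.74 against 23.9 CPM), Frat2 and Ppp1r15a were lower. Xist cells were 86.6% of the sexed cells of the IL12 spleen, 48.1% of the IL10 and 69.7% of the null spleen. NK cells held more Pim2 (584 against 80.0 CPM), Batf3, Glrx and Cd38 (119 against 22.5 CPM), and less Fos, Ier2 (61.7 against 589 CPM), Zfp36 and Fosb. Handling medians were -0.44 (-0.51 to -0.40) in B cells and -0.52 (-0.66 to -0.40, 2 higher and 9 lower of 18) in T cells. Shares differed by -13.6 points (-14.8 to -12.4) for T cells, -6.56 points (-7.92 to -5.2) for B cells and 7.04 points (6.26 to 7.83) for macrophages with monocytes, and with the erythroid cells left out by -9.9, 0.742 and 9.8.

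IP cells were set beside spleen cells of the same implant, although the tissues yield cells in different ways. B cells of the IP cavity carried more genes of B-1 and innate-like B cells with each implant, with medians of 1.56 (1.48 to 1.67) for IL10, 1.39 (1.18 to 1.52) for IL12 and 1.79 (1.66 to 1.94) for null. T cells around the implants held more proliferation transcripts than those of the spleen with IL10 (median 1.68, 1.52 to 1.81) and null (1.47, 1.41 to 1.65), and lay closer to them with IL12 (0.31, 0.26 to 0.35, 0 of 24 higher by size), although the null value was -0.075 in Xist cells alone and the IL12 value -0.047 in Y cells alone. The proliferation gene Birc5 was seen in 20 of the 283 null IP T cells. The interferon-gamma median of T cells, IP against spleen, was above 0 with null (0.72, 0.62 to 0.86, 11 of 24 higher) and near 0 with IL10 (0.074, -0.079 to 0.25) and IL12 (-0.063, -0.15 to -0.023). The null value was -0.0081 in Xist cells alone and the IL12 value 0.041 with doublets kept. Xist cells were 24.4% of the sexed null T cells in the IP cavity and 92.3% in the spleen.

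Responses to IL12 in T cells went together in both tissues: across 9758 genes the log2 ratios against null had a Pearson r of 0.700 and a Spearman rho of 0.699, and 329 of 331 genes at least 2-fold apart in both went the same way. For IL12 in B cells r was 0.418 and rho 0.274 (8923 genes, 45 of 45 the same way), and in NK cells r was 0.418 and rho 0.382 (5922 genes, 152 of 163). For IL10, r was 0.197 and rho 0.108 in T cells (8447 genes, 14 of 16), r 0.25 and rho 0.138 in B cells (9415 genes, 14 of 15), and r 0.359 and rho 0.322 in NK cells (5282 genes, 18 of 18). These 6 correlations run across genes, which are not independent replicates.

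**Figure D5:**
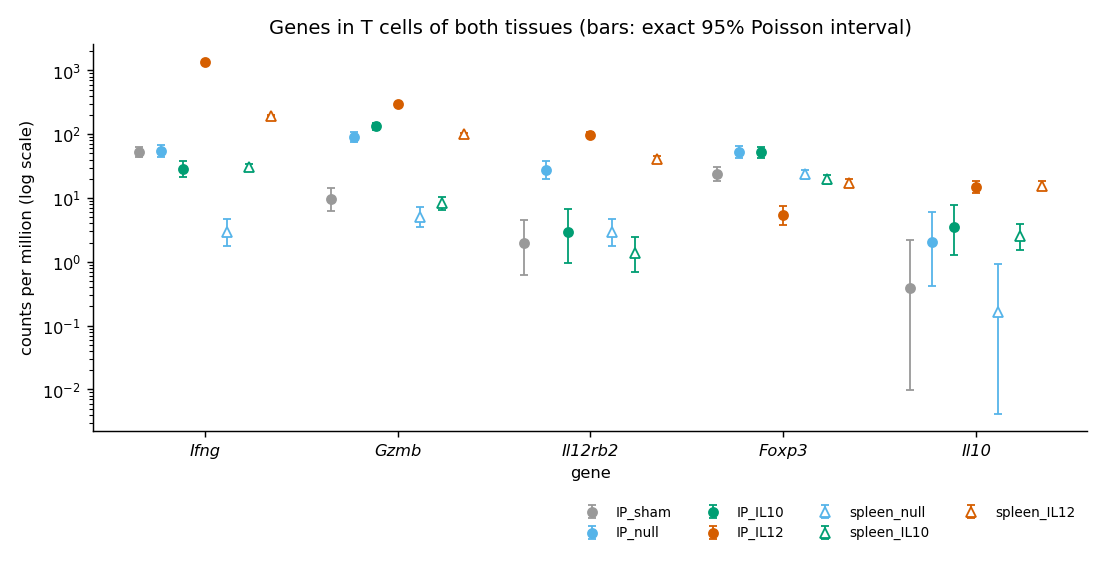
Expression of Ifng, Gzmb, Il12rb2, Foxp3 and Il10 (x axis) in T cells in CPM on a log scale (y axis), with circles for the IP cavity, triangles for the spleen, colours for the implant and exact 95% Poisson intervals. Ifng reaches 1350 CPM in the IP cavity and 193 CPM in the spleen with IL12, against 55.6 and 2.97 CPM with null.

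The mouse genes of the implanted cytokines were themselves rare. Il10 (ENSMUSG00000016529) was at 15 CPM in IP T cells with IL12, 3.52 with IL10, 2.03 with null and 0.39 with sham. It was at 15.7, 2.5 and 0.165 CPM in spleen T cells with IL12, IL10 and null. In IP macrophages it was 4.49 CPM with IL10 and 1.8 CPM with sham, and without a count with null. Il12b (ENSMUSG00000004296) was seen in dendritic cells, at 43.4 CPM in the IP cavity with IL12 and without a count with the other implants there. In the spleen it was at 21.5, 0.533 and 42.2 CPM with IL12, IL10 and null. Il12a lay in B cells, from 7.75 CPM in the sham IP library to 36.3 CPM in the IL10 spleen. The receptor gene Il12rb1 was higher with IL12 than with null in IP NK cells (113 against 28.7 CPM) and spleen T cells (28.8 against 4.46 CPM). Il10ra was at 67.8 CPM in IP macrophages with IL10, 151 with IL12, 112 with null and 121 with sham. The list of these cytokines, their receptors and signalling genes had a median of -0.093 (-0.29 to 0.14) in IP T cells, IL12 against null. Gata6, the factor of resident peritoneal macrophages, was at 27.2, 11.5, 57.9 and 44.9 CPM in IP macrophages with IL10, IL12, null and sham, and Ccr2 at 1592, 411, 974 and 1628 CPM in monocytes.

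On the mouse assembly mm10, Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 at 92321347 to 92328079 and Spp1 (ENSMUSG00000029304) at 104435118 to 104441050. Arg1 (ENSMUSG00000019987) lies on chromosome 10 at 24915221 to 24927484 and Ifng (ENSMUSG00000055170) at 118441046 to 118445892. Cd163 (ENSMUSG00000008845) lies on chromosome 6 at 124304656 to 124330527, and on chromosome 16 lie Retnla (ENSMUSG00000061100) at 48842551 to 48844461 and Socs1 (ENSMUSG00000038037) at 10782240 to 10785536.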

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

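Chosen only after the result was seen were the tests of handling, of a state of part of the null pool's mice and of a weaker lysis, and the split into Xist cells and Y cells and the joint macrophage and monocyte class.

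In IP macrophages and monocytes the interferon-gamma list was lower with IL10 than with null, at -2.13, and causes other than secreted IL10 were weighed. A different mix of female and male cells is argued against as the whole cause by Y cells alone, where the median stayed at -2.20 (-2.41 to -2.13), although the bound set in advance asked for this in Xist cells too, and there it was 0.04. The null Xist cells held the list low, which left little room to fall. Handling of the cells cannot be told apart from the other causes. In spleen monocytes handling genes differed by 1.79 between the same implants and the interferon-gamma median was -0.27 (-0.37 to -0.14), but null spleen monocytes held the list at a median of 12.7 CPM against 100.3 in the null IP cells, which left little room to fall. A state of part of the mice in the null pool is in line with the null library itself, where Y cells exceeded Xist cells by 2.18 (1.94 to 2.43). It stays open whether that state is a response of male mice to the null implant, an event in some mice of the pool, or what IL10 acts on, since neither sex nor mouse was varied by the labels and none of this was tested.

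Erythroid cells took 18.1% of the IL12 and 0.643% of the null spleen. Red cells left by a weaker lysis are argued against by haemoglobin, which took 0.0785% of the UMIs of the class, and by 4720 genes in its median cell against 1649 in the library. On free haemoglobin RNA 13 other erythroid markers cannot decide (median ratio to ambient 2.43), as such markers named the class. A single mouse as the source is argued against by the rarer sex, which made 16.7% (lower bound 15) of the sexed erythroid cells. A response of erythroid cells to IL12, or to another state of these mice, stays open and was not tested.

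Unnamed clusters of low depth took 24.5% of the IL12 IP cells. Cells that lost cytoplasmic RNA are argued against by mitochondrial shares of 1.06 and 1.08 times that of macrophages. Free RNA in the droplets cannot be told apart from cells of low RNA content: one cluster correlated across genes at 0.971 with the nearest named cluster and 0.947 with the ambient profile, the other at 0.937 and 0.95, so the smaller difference was -0.0122. What these barcodes are stays open, and with them the IL12 shares of every class.

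Values that pointed opposite ways between tissues were singled out, and the difference between the tissues was not tested. For IL10 against null, T cells differed by -3.75 points in the IP cavity and 11.4 in the spleen, macrophages by 19.1 and -2.07, and dendritic cells by 1.7 and -1.75. The joint macrophage and monocyte class differed by 12.2 and -3.39 points. The IP macrophage value turned to -7.53 at a minimum of 1000 UMIs per cell, while the joint value kept its direction under all settings (1.72 to 25.4). For IL12 against null, macrophages differed by -2.53 and 8.12 points and monocytes by 6.91 and -4.46. Each of these 4 values turned under other settings, and so did the IP value of the joint class (4.38, and 3.65 in the spleen), to -15.1 at a minimum of 1000 UMIs per cell and under 4 other settings. The interferon-gamma list of null against sham was singled out because Xist cells and Y cells pointed opposite ways, again without a test of the difference: -0.90 and 1.89 in macrophages, -0.96 and 1.97 in monocytes, and -0.55 and 2.40 in both classes together.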

How the results depend on the processing

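The joint macrophage and monocyte class, Xist cells alone, Y cells alone and erythroid cells left out were chosen only after the result was seen, and all other settings before. Of 281 values of the 27 main results under these settings, 135 stayed close, 126 changed in size and 20 changed direction. A value stayed close where it lay within the 95% counting interval of the main value, changed direction where it had the other sign and that interval left out 0, and changed in size otherwise. The main interval of T cells, IP against spleen with IL10, spans 0, so a value of the other sign is not counted there as changed direction. Of 2040 values of 180 other results, 1303 stayed close, 687 changed in size and 50 changed direction, and of 1800 values of 200 named genes, 1535, 264 and 1, where stayed close meant within 0.5 log2 and any other sign counted as direction. The macrophage and monocyte shares were the least stable results, and the interferon-gamma list of IL12 against null or IL10 never changed direction in the IP cavity or in spleen B cells. IL10 macrophages lay mostly in a cluster with a median of 1114 UMIs, so a minimum of 1000 UMIs removes many of them by construction. Leaving out the erythroid cells raises every other share of the IL12 spleen by construction. The cause of the other changes was not tested.

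Shares of cells in the main comparisons, as points of first less second with the main value in brackets, were these. For macrophages, null against sham (-13.4) turned to 7.76 with 1000 UMIs, 2.99 with 200 UMIs, 2.49 at 5% mitochondrial UMIs, 5.62 at resolution 2.0, 2.82 by marker counts and 8.97 with both classes together. It was -22.3 at 20% mitochondrial UMIs. For macrophages, IL10 against null (19.1) turned to -7.53 with 1000 UMIs. It was 5.44 with 200 UMIs, 32.6 at 20% mitochondrial UMIs, 2.83 at 5% mitochondrial UMIs, 16.1 with doublets kept, 7.8 at resolution 2.0, 4.63 by marker counts and 12.2 with both classes together. For macrophages, IL12 against null (-2.53) turned to 12.3 at 20% mitochondrial UMIs and 4.38 with both classes together. It was -8.57 with 1000 UMIs, -20.0 at 5% mitochondrial UMIs and -11.9 at resolution 2.0. For macrophages, IL12 against IL10 (-21.7) was -1.03 with 1000 UMIs, -8.8 with 200 UMIs, -18.1 with doublets kept, -19.7 at resolution 2.0, -7.81 by marker counts and -7.78 with both classes together. For spleen T cells, IL10 against null (11.4) was 9.81 with 1000 UMIs and 9.88 by marker counts. For spleen T cells, IL12 against null (-2.17) turned to 1.4 without erythroid cells. It was -4.71 with 200 UMIs, -3.24 at resolution 2.0 and -4.87 by marker counts. For spleen T cells, IL12 against IL10 (-13.6) was -15 with 200 UMIs, -15.1 at resolution 2.0 and -9.9 without erythroid cells. For both classes, null against sham (8.97) was 0.0648 at 20% mitochondrial UMIs, 4.82 at 5% mitochondrial UMIs and 6.22 by marker counts. For both classes, IL10 against null (12.2) was 8.03 with 1000 UMIs, 1.72 with 200 UMIs, 25.4 at 20% mitochondrial UMIs, 16.7 at 5% mitochondrial UMIs, 21.2 at resolution 2.0 and 1.98 by marker counts. For both classes, IL12 against null (4.38) turned to -15.1 with 1000 UMIs, -8.04 with 200 UMIs, -25.5 at 5% mitochondrial UMIs, -25.9 with doublets kept and -6.92 by marker counts. It was 17.7 at 20% mitochondrial UMIs and 14.1 at resolution 2.0. For both classes, IL12 against IL10 (-7.78) was -23.1 with 1000 UMIs, -9.76 with 200 UMIs, -42.2 at 5% mitochondrial UMIs and -37.1 with doublets kept.

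Medians of the interferon-gamma list, in log2, and the correlations between tissues were these. In macrophages, null against sham (1.43) turned to -0.90 in Xist cells. It was 2.32 with 1000 UMIs, 2.06 at 5% mitochondrial UMIs, 2.28 at resolution 2.0, 1.98 with 1 CPM added, 0.96 by cell means, 2.02 with both classes together and 1.89 in Y cells. In macrophages, IL10 against null (-1.48) was -2.32 with 1000 UMIs, -2.32 at 5% mitochondrial UMIs, -2.33 at resolution 2.0, -2.29 with 1 CPM added, -1.41 with 1 count, -1.06 by cell means, -2.13 with both classes together and -2.11 in Y cells. In macrophages, IL12 against null (1.61) was 0.82 with 1000 UMIs, 0.92 at 5% mitochondrial UMIs, 0.82 at resolution 2.0, 1.73 with TMM, 1.72 with DESeq2, 1.77 with 1 CPM added, 2.07 by cell means, 1.24 with both classes together, 3.14 in Xist cells and 1.18 in Y cells. In macrophages, IL12 against IL10 (3.28) was 3.18 with 1000 UMIs, 3.39 with TMM, 3.38 with DESeq2 and 4.4 with 1 CPM added. In spleen B cells, IL10 against null (-0.11) was -0.082 with DESeq2, -0.28 with 1 CPM added, -0.20 less ambient RNA, -0.076 in Xist cells and -0.40 in Y cells. In spleen B cells, IL12 against null (1.35) was 2.49 with 1 CPM added, 1.25 with 1 count, 2.04 with 100 counts, 1.5 by cell means and 1.71 in Y cells. In spleen B cells, IL12 against IL10 (1.57) was 1.41 with TMM, 1.43 with DESeq2, 2.54 with 1 CPM added, 1.39 with 1 count, 2.2 with 100 counts, 1.68 by cell means, 1.52 in Xist cells and 2.15 in Y cells. In both classes, null against sham (2.02) turned to -0.55 in Xist cells. It was 2.13 at resolution 2.0, 2.92 with 1 CPM added, 1.62 by cell means and 2.4 in Y cells. In both classes, IL10 against null (-2.13) turned to 0.036 in Xist cells. It was -1.96 at 5% mitochondrial UMIs, -2.22 at resolution 2.0, -3.14 with 1 CPM added, -1.83 by cell means and -2.2 in Y cells. In both classes, IL12 against null (1.24) was 0.99 with 1000 UMIs, 1.09 at 5% mitochondrial UMIs, 1.08 with doublets kept, 1.14 at resolution 2.0, 1.4 with TMM, 1.39 with DESeq2, 1.31 with 1 CPM added, 1.53 by cell means, 3.1 in Xist cells and 0.94 in Y cells. In both classes, IL12 against IL10 (3.31) was 3.24 with 1000 UMIs, 3.46 with TMM, 3.44 with DESeq2 and 4.7 with 1 CPM added. In T cells, IP against spleen with IL10 (0.074) was -0.21 in Xist cells. In T cells, IP against spleen with IL12 (-0.063) turned to 0.041 with doublets kept. It was -0.20 less ambient RNA. In T cells, IP against spleen with null (0.72) turned to -0.0081 in Xist cells. It was 0.91 with 1000 UMIs and 0.99 by cell means. The correlation across genes of T cell ratios, IL10 against null, (0.197) was 0.153 with 1 CPM added, 0.175 with 1 count, 0.29 with 100 counts and 0.154 less ambient RNA. The correlation across genes of T cell ratios, IL12 against null, (0.7) was 0.708 with 1000 UMIs, 0.707 at 5% mitochondrial UMIs, 0.689 with doublets kept, 0.677 at resolution 2.0, 0.657 with 1 CPM added, 0.69 with 1 count, 0.619 by cell means and 0.664 less ambient RNA.

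Among the other shares, those that changed direction were these. For monocytes, IL10 against null (-6.97) turned to 15.6 with 1000 UMIs, 13.9 at 5% mitochondrial UMIs and 13.4 at resolution 2.0. For monocytes, IL12 against null (6.91) turned to -6.49 with 1000 UMIs, -4.67 with 200 UMIs, -5.43 at 5% mitochondrial UMIs, -23.9 with doublets kept and -3.73 by marker counts. For monocytes, IL12 against IL10 (13.9) turned to -22.1 with 1000 UMIs, -0.956 with 200 UMIs, -19.3 at 5% mitochondrial UMIs, -19 with doublets kept and -1.08 by marker counts. For spleen monocytes, IL10 against null (-1.32) turned to 0.273 with 200 UMIs and 0.212 by marker counts. For spleen macrophages, IL12 against null (8.12) turned to -0.809 with 200 UMIs and -0.0881 by marker counts. For spleen monocytes, IL12 against null (-4.46) turned to 3.14 with 200 UMIs and 2.9 by marker counts. For spleen neutrophils, IL12 against null (-7.13) turned to 0.0518 with 200 UMIs. For spleen dendritic cells, IL12 against null (-0.742) turned to 0.0761 without erythroid cells. For spleen B cells, IL12 against IL10 (-6.56) turned to 0.742 without erythroid cells. For spleen monocytes, IL12 against IL10 (-3.15) turned to 2.87 with 200 UMIs and 2.69 by marker counts.

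Among the other lists and genes, these changed direction. Proliferation list, IP against spleen with IL12 in T cells (0.31) turned to -0.047 in Y cells. Proliferation list, IP against spleen with null in T cells (1.47) turned to -0.075 in Xist cells. Type I interferon list, null against sham in macrophages (0.51) turned to -0.32 in Xist cells. MHC class II presentation list, null against sham in macrophages (0.40) turned to -0.96 in Xist cells. Fibrosis and foreign body list, null against sham in macrophages (0.076) turned to -0.023 with 100 counts. Monocyte-derived macrophage list, null against sham in macrophages (0.73) turned to -0.98 in Xist cells and -0.56 in Y cells. MHC class II presentation list, IL10 against null in macrophages (-1.12) turned to 0.52 in Xist cells. MHC class I presentation list, IL10 against null in macrophages (-0.86) turned to 0.46 in Xist cells. Resident macrophage list, IL10 against null in macrophages (-0.43) turned to 0.93 with 1000 UMIs, 0.82 at 5% mitochondrial UMIs and 0.99 at resolution 2.0. Monocyte-derived macrophage list, IL10 against null in macrophages (-0.93) turned to 0.56 in Xist cells. Interferon-gamma list, null against sham in monocytes (1.47) turned to -0.79 with 1000 UMIs, -0.79 at 5% mitochondrial UMIs and -0.96 in Xist cells. Interferon-gamma list, IL10 against null in monocytes (-2.22) turned to 0.19 in Xist cells. Interferon-gamma list, IL10 against null in B cells (-0.46) turned to 0.050 in Xist cells. Type 1 lymphocyte list, null against sham in T cells (0.74) turned to -0.24 in Xist cells. Type 1 lymphocyte list, IL10 against null in T cells (-0.49) turned to 0.47 in Xist cells. Interferon-gamma list, IL10 against null in spleen T cells (-0.088) turned to 0.068 with TMM and 0.078 with DESeq2. Proliferation list, IL10 against null in spleen NK cells (1.24) turned to -0.49 in Xist cells. Interferon-gamma list, IL10 against null in spleen monocytes (-0.27) turned to 0.14 in Xist cells. B activation and germinal centre list, IL12 against null in spleen B cells (0.54) turned to -0.032 in Y cells. Ribosomal proteins list, IL12 against null in spleen B cells (0.040) turned to -0.024 with TMM. Fcrls, IL12 against null in macrophages (-2.27) turned to 0.068 with 1000 UMIs.

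No paired analysis was possible because each group is a single library and the labels pair none of the mice. The pools of 6 mice hold both sexes in unknown numbers, each comparison of implants is also one between pools, and the null IP library has the fewest UMIs, so low counts limit its comparisons most.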

Other observations

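The look at testis genes and the values given for Xist cells and Y cells were chosen only after the result was seen.

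Transcripts of testis genes were met in unexpected places. Tnp2 had 388 UMIs and Prm1 214 in the IL12 IP library, and 291 and 48 in the IL12 spleen, against 18 and 15 in the null IP library and 10 and 0 in the null spleen. Socs1, a suppressor of cytokine signalling that interferon-gamma induces, starts at 10785536 on the minus strand of chromosome 16 and had 13123 UMIs in the IL12 IP library and 11290 in the IL12 spleen, and Tnp2 (10787936 to 10788660) and Prm1 (10796326 to 10805839) lie upstream of it on the same strand. Whether these UMIs come from transcripts that share sequence with Socs1 was not tested. Apart from these, a single barcode of the IL10 IP library with 168259 UMIs and 9031 genes held Ldhc (1398 UMIs, 3 in all other IP cells), Meig1 (1205) and Fabp9 (699) and no Ptprc or Adgre1, and the next deepest barcode of that library held 40509 UMIs.

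As a class, erythroid cells of the IL12 spleen held precursor genes above the ambient profile. These were the receptor genes Tfrc (transferrin, 177 against 74.3 CPM) and Epor (erythropoietin, 128 against 41.3), and Hbb-bs (317 against 165). Division genes were near the ambient profile (Top2a 370.2 against 303.5 CPM, Mki67 385 against 357). They were not below those of 69 null erythroid cells (276.5 and 343, ambient 59.6 and 82.2). Plasma cells took 1.8% of the IL12 spleen, 0.643% of the null and 0.359% of the IL10 spleen, and progenitors 5.4%, 4.42% and 2.52%. Within the null IP library the difference between Y cells and Xist cells on the interferon-gamma list reached beyond macrophages and monocytes, at 1.07 (0.56 to 1.23) in dendritic cells, 0.82 (0.56 to 1.08) in T cells and 0.65 (0.41 to 0.80) in B cells. Handling genes differed alike in both sets of cells, IL10 against null, at 1.39 in Xist cells and 1.40 in Y cells of the joint macrophage and monocyte class.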
